A study of Homo sapiens with 8 samples.

How the data were processed

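Nuclear matrix DNA and digested nuclei DNA were prepared from MCF-10A and MDA-MB-231 cells. Per the labels' protocols, cells were crosslinked with formaldehyde, digested with 6 restriction enzymes and extracted with ammonium sulfate, and the DNA that remained was sonicated and sequenced on an Illumina instrument. The labels give 8 samples in 4 groups, each with 2 biological replicates. The deposited peak lists cover the 4 nuclear matrix libraries, with 1 list per library and no pooling of replicates. The 4 digested nuclei samples were not analysed here, so no value of the background is set beside the peaks.

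Per the submitters' processing notes, CASAVA 1.6, Bowtie2, MACS 1.4 and bedtools were used with the hg19 build. The role of each tool, its parameters and the library used as control for peak calling are not given in the sources used here. Each list gives a chromosome, start, end, name and score per peak. The score is the peak caller's own value, deposited by the authors without normalization between libraries. By the convention of MACS 1.4 it is minus 10 times the log10 of the peak's p-value, and the lowest score in each list is about 50. Scores were used to describe, rank and filter peaks within a list. The same score minimum was applied to every list, and values given for several lists side by side are not on a common scale of enrichment. Read depth is unknown. MACS 1.4 calls more peaks from deeper libraries and from libraries with higher enrichment, so a number of peaks mixes depth, enrichment and the amount of bound DNA. How reads of repeated sequence were placed is not given in the sources used here, and such reads affect peaks beside centromeres in particular.

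From the lists, the number of peaks, the covered length, and the median width and score were taken per library. The 2 lines were compared by an exact two-sided permutation test on the log2 number of peaks. Peaks on the 24 chromosomes were used for all tests of position, and peaks on unplaced sequences were counted apart. A peak was shared when it overlapped a peak of another library by at least 1 bp. The shorter list was placed at random within its own chromosomes 10000 times, a permutation test of peak positions, and the one-sided p was adjusted by the Benjamini-Hochberg method over the 6 pairs of libraries. Peaks per chromosome were set against chromosome length by a Monte Carlo chi-square test with 10000 draws and by exact binomial tests adjusted over 24 chromosomes. The median distance to the nearest peak, and the share of peaks within 5 Mb of a centromere gap or chromosome end, were set against 1000 random placements each, two-sided, with 0.002 as the smallest p. For the share near gaps and ends, random peaks were kept out of the centromere gaps and of the unsequenced short arms of chromosomes 13, 14, 15 and 22. Random placement did not model which sequences reads can be mapped to, and peaks within a library are not replicates, so these tests describe single libraries. Shares have exact Clopper-Pearson 95% intervals, and the limit for a share of 0 is 3 counts of the total. The threshold was 0.05 on adjusted p-values.

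Chromosome lengths came from the hg19 table of GenomeInfoDb 1.38.1. Centromere gap positions of hg19 were entered from memory, because no reference of that build was given, and were checked on the peaks. No peak of any library reached over 50 bp into a gap, where random placement of replicate 1 of MDA-MB-231 gave 94.1 such peaks. That library had a peak within 1 kb of 4 gaps and within 100 kb of 19. Large heterochromatin gaps apart from the centromere gap were not part of the 5 Mb rule. Peaks were not filtered here for regions known to give artefact signal, because no list of them was given. The gene table given for naming was of another assembly than hg19, so its coordinates were not used. Gene annotation, sequence content, restriction site density and 19 gene lists fixed in advance could therefore not be tested, and no gene is named. Score and width of peaks shared between replicates were not compared, because 0 peaks were shared.

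Tests and alternatives were fixed before the data were examined, except where the text says otherwise. Regions were named by a rule fixed at the same time. It took all regions shared by both replicates of a line or by both lines (the 10 with the highest summed score if over 15), the 5 highest-scored peaks per library, and the 3 chromosomes with most and the 3 with fewest peaks per Mb. Where more than 3 chromosomes held 0 peaks, their number is given. The test of positions near centromere gaps and ends was added after peak positions had been seen. Distances of 2, 5 and 10 Mb were looked at before 5 Mb was taken as the reported one. The count of peaks per chromosome without the 5 Mb beside each gap and without the unsequenced short arms, the clusters of 10 or more peaks, and the regions named for their number of peaks, were also chosen after the values were seen. The alternatives fixed in advance were a score minimum of 100, other definitions of a shared peak (50% of the shorter peak, or within 1 or 10 kb), other random placements, merging of nearby peaks, leaving out chromosome Y, and leaving out each replicate. The tests of overlap, of the share near centromere gaps and of single chromosomes were checked on simulated lists with planted shared peaks, peaks moved next to gaps, or a doubled chromosome. The other tests were not simulated. Simulated calls of overlap and of the share near gaps were made on p-values before adjustment. They also used fewer placements than the reported tests, so their rates can differ from those of the reported tests. With 10% of peaks moved, the test of the share near gaps made a call in 27.5% and 15% of simulations of replicates 1 and 2 of MCF-10A, and in 100% and 90% of those of MDA-MB-231. With 20% of peaks moved, it made a call in 87.5% of simulations of replicate 2 of MCF-10A and in 100% of those of the other libraries. A doubled chromosome 7 was called in 100% of simulations of replicate 1 of MDA-MB-231. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.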

Results

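MAR-seq sequences the DNA that stays bound to the nuclear matrix, the protein scaffold left after cells are crosslinked, their chromatin is cut with restriction enzymes and the released DNA is washed out. The series holds 8 samples of human mammary cells. MCF-10A is a non-tumorigenic breast epithelial line, and MDA-MB-231 is a metastatic breast adenocarcinoma line. For each line the labels give 2 biological replicates of nuclear matrix DNA and 2 of digested nuclei as background. The 4 nuclear matrix libraries each had a deposited list of peaks, which are regions of read enrichment called separately in that library. The 4 digested nuclei samples were not analysed here. Read depth per library is unknown, so the number of peaks called and their scores describe each list and do not measure the amount of bound DNA. Positions are in hg19 and count from 1.

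The number of peaks per library was compared first, to ask how many regions were called in each line. Replicate 1 of MDA-MB-231 held 4225 peaks that covered 4059 kb. Its replicate 2 held 121 peaks that covered 231.9 kb. In MCF-10A, replicate 1 held 43 peaks over 65.7 kb and replicate 2 held 30 peaks over 16.4 kb. The mean was 2173 ± 2902 peaks in MDA-MB-231 and 36.5 ± 9.19 in MCF-10A (SD, n = 2 per line). Both MDA-MB-231 libraries held more peaks than both MCF-10A libraries, by 98.3-fold between the libraries numbered 1 and by 4.03-fold between those numbered 2. The 2 replicates of MDA-MB-231 differed from each other by 34.9-fold and those of MCF-10A by 1.43-fold. The difference between lines, 4.32 on the log2 scale, gave an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow, so the test could not have passed whatever the values. Without replicate 1 of MDA-MB-231 the difference was 1.75 on the log2 scale.

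Scores are the authors' own value per peak and start at about 50 in every list. They depend on read depth, which is unknown, so the following values describe each list and do not measure enrichment between libraries. The median score was 70.5 in replicate 1 and 54.7 in replicate 2 of MCF-10A, and 73.4 in replicate 1 and 55.4 in replicate 2 of MDA-MB-231. A score of at least 100 was reached by 11 of 43 peaks in replicate 1 of MCF-10A and by 1261 of 4225 in replicate 1 of MDA-MB-231. It was reached by 0 peaks in either replicate 2, where the highest scores were 80.98 for MCF-10A and 95.02 for MDA-MB-231. Median peak width was 914 bp and 531.5 bp in replicates 1 and 2 of MCF-10A, and 700.0 bp and 1377 bp in replicates 1 and 2 of MDA-MB-231.

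**Figure D1:**
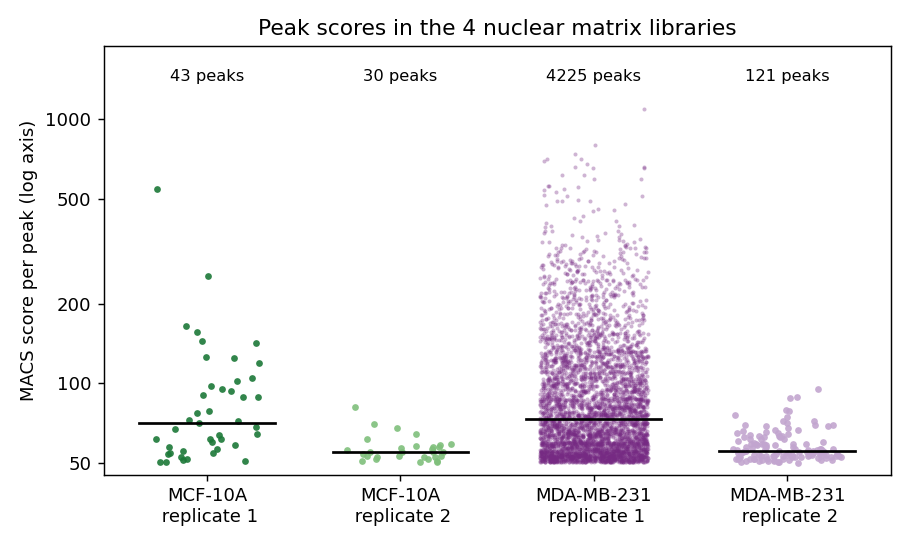
Score of each peak (log axis, no unit) in the 4 nuclear matrix libraries, with 1 point per peak spread sideways at random and a black line at the median. Both replicates 2 lie below a score of 100, while 11 peaks of MCF-10A replicate 1 and 1261 peaks of MDA-MB-231 replicate 1 lie at or above it.

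The strongest regions of each library stood at different places. The highest score of replicate 1 of MCF-10A, 543.3, belonged to chromosome 7 from 56437922 to 56443003, which lay 1.61 Mb from the centromere gap of the assembly. It was followed by regions of chromosome 1 (2583370 to 2587998, score 254.1), chromosome 16 (33293707 to 33294521, score 164.3), chromosome 10 (1281637 to 1282469, score 155.7) and chromosome 17 (21902118 to 21903968, score 144.4). Among the peaks of replicate 2 of MCF-10A the highest score, 80.98, belonged to chromosome 20 from 46523463 to 46524343. The next were on chromosome 1 (1649105 to 1649888, score 69.8), chromosome 5 (133672283 to 133672904, score 67.3, and 166317505 to 166318007, score 64.2) and chromosome 19 (42409636 to 42410156, score 61.6). Among those of replicate 1 of MDA-MB-231 the top score, 1100, belonged to an 8949 bp region of chromosome 10 from 42659454 to 42668402, which lay 0.4045 Mb from the centromere gap. A further region 0.5503 Mb from that gap, 42805208 to 42810883, had a score of 742.3. The other three were on chromosome 5 (86214310 to 86218169, score 803.3), chromosome 4 (64066673 to 64069709, score 709.4) and chromosome 7 (64686370 to 64689661, score 706.5). In replicate 2 of MDA-MB-231 the top score, 95.02, belonged to chromosome X from 50868064 to 50868990. It was followed by regions of chromosome 19 (34302040 to 34305120, score 88.2), chromosome 7 (149520420 to 149525224, score 87.9) and chromosome 11 (1001346 to 1003397, score 79.4, and 1584857 to 1589320, score 78.5).

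No region was shared by the 2 replicates of either line. Of the 30 peaks of replicate 2 of MCF-10A, 0 touched a peak of replicate 1, which allows a share of up to 10%. Of the 119 chromosomal peaks of replicate 2 of MDA-MB-231, 0 touched any of the 4060 chromosomal peaks of replicate 1, which allows up to 2.52%. Such limits and the intervals below cover counting error only. Random placement of the shorter list within its chromosomes gave on average 0.0013 shared peaks in MCF-10A and 0.478 in MDA-MB-231, and 61.97% of the random draws for MDA-MB-231 also shared 0. The count of 0 was therefore not below what chance gives in either line, nor was there an excess over chance (one-sided permutation of peak positions, adjusted p = 1 for both lines). In simulated lists of the same sizes, 3 truly shared peaks were called in 100% of simulations of the MDA-MB-231 pair and 1 shared peak in 5%. For the MCF-10A pair, 1 shared peak was called in 100%.

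Between the lines, 3 regions were shared, all of them between the libraries numbered 1. These were 3 of the 42 chromosomal peaks of replicate 1 of MCF-10A (7.14%, exact 95% interval 1.498 to 19.5), against 0.136 on random placement (one-sided permutation of peak positions, p = 0.0005, adjusted p = 0.003 over 6 pairs of libraries). When peaks were placed at random within 1 Mb of their own position, which keeps regional density, 0.408 shared peaks were expected (permutation p = 0.0072). In the direction of the longer list they made up 0.071% of all 4225 peaks of replicate 1 of MDA-MB-231. The shared region of chromosome 1 ran from 2583370 to 2587998, 2.58 Mb from the chromosome end, with a score of 254.1 in MCF-10A and 126.6 in MDA-MB-231. The region of chromosome 17 from 21902118 to 21903968, 0.359 Mb from the centromere gap, scored 144.4 in MCF-10A and 51.3 in MDA-MB-231. The region of chromosome 8 from 82754435 to 82755091 scored 50.03 in MCF-10A, the lowest score in that list, and 65.6 in MDA-MB-231. The other cross-line pairs shared 0 peaks, against random means between 0.0049 and 0.0581. Over both libraries of each line, 3 of 72 MCF-10A peaks were shared (permutation p = 0.0019), and 0 were shared without replicate 1 of MCF-10A or without replicate 1 of MDA-MB-231. With only peaks of score 100 or more in the libraries numbered 1, 1 peak was shared (permutation p = 0.0185). No list of regions known to give artefact signal was at hand, so peaks were not filtered for them. Whether the shared regions are of that kind was not tested.

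The distribution of peaks over chromosomes was set against chromosome length to ask whether some chromosomes held more peaks than others for their length. In replicate 1 of MDA-MB-231, 5 chromosomes held more peaks and 8 held fewer than their length gives (exact two-sided binomial tests, adjusted over 24 chromosomes). The densest was chromosome 7, with 358 peaks or 2.25 per Mb, 1.71 times the length-based number (exact 95% interval 1.55 to 1.89, adjusted p = 9.71e-21). By the same exact test, chromosome 21 was next with 92 peaks or 1.91 per Mb (1.46 times, adjusted p = 0.00175) and chromosome 5 with 321 peaks or 1.77 per Mb (1.35 times, adjusted p = 5.86e-07), and chromosomes X and 11 were also higher (1.33 and 1.22 times). The sparsest were chromosome 15 (68 peaks, 0.663 per Mb, 0.506 times the length-based number), chromosome 13 (101 peaks, 0.669 times) and chromosome 17 (75 peaks, 0.704 times), and chromosomes 1, 2, 3, 8 and 18 were also lower. The distribution as a whole gave a Monte Carlo p of 0.0001, the smallest its draws can give. A further count was chosen after seeing the data. It left out the 5 Mb beside each gap and the unsequenced short arms of chromosomes 13, 14, 15 and 22. In it, 6 chromosomes were higher and 9 lower. The ratio of chromosome 21 turned to 0.579 (exact 95% interval 0.367 to 0.866, exact binomial test, adjusted p = 0.0123). Its length kept the part of its short arm over 5 Mb from the gap, and any part without sequence lowers that ratio. Chromosomes 16, 22 and Y also became low (0.708, 0.554 and 0.457 times), and 4 and 14 high (1.21 and 1.25 times). With peaks within 100 kb also joined, 9 chromosomes passed. Chromosomes 5, X, 7 and 4 were higher (1.43, 1.44, 1.23 and 1.22 times, exact binomial test, adjusted p = 5.82e-06, 1.68e-05, 0.0338 and 0.0207). Chromosomes Y, 15, 16, 1 and 9 were lower (0.150, 0.583, 0.719, 0.741 and 0.768 times, exact binomial test, adjusted p = 1.11e-09, 0.00117, 0.0484, 0.000383 and 0.0338). The lengths keep large heterochromatin gaps apart from the centromere gap, and that of Y includes a large part without sequence. Low ratios such as those of chromosomes 1, 9 and 16 were therefore not separated from missing sequence. Whether this line carries a Y chromosome was not examined. Of the chromosomes called on all peaks, 11 and 21 and 13, 17, 2, 3, 8 and 18 did not pass in that count (exact binomial test, adjusted p from 0.11 to 0.592). With only peaks of score 100 or more, 4 chromosomes passed the threshold in place of 13.

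In replicate 2 of MDA-MB-231, 3 chromosomes held more peaks than their length gives. Of these, chromosome 11 was nearest the threshold and was also higher in replicate 1 on all peaks. Away from centromere gaps and with peaks joined, chromosome 11 did not pass in replicate 1 (1.11 times, exact binomial test, adjusted p = 0.335). The difference between the replicates was not tested by chromosome. Chromosome 19, the most gene-dense human chromosome, held 16 of its 119 peaks, 7.04 times the length-based number (exact 95% interval 4.13 to 10.9, adjusted p = 3.15e-08). Chromosome 20 held 9 peaks (3.71 times, exact binomial test, adjusted p = 0.00934) and chromosome 11 held 12 (2.31 times, adjusted p = 0.0476), and without chromosome Y in the test 2 chromosomes passed in place of 3. Chromosome 17 came after chromosomes 19 and 20 by peaks per Mb, with 8 peaks or 0.0985 per Mb, and did not pass after adjustment (exact binomial test, adjusted p = 0.0808). Chromosomes 16, 18 and Y held 0 peaks. Chromosome 7 held 6 peaks, 0.981 times the length-based number (0.364 to 2.07), and a doubling of that chromosome was called in 23% of simulations of this list. In MCF-10A, 0 chromosomes passed the threshold in either replicate, with a Monte Carlo p of 0.0777 for replicate 1 and 0.0021 for replicate 2. The densest chromosomes were 19, 16 and 1 in replicate 1, with 3, 3 and 7 peaks, and 20, 19 and 12 in replicate 2, with 4, 2 and 4 peaks. There were 9 chromosomes with 0 peaks in replicate 1 and 11 in replicate 2. At these list lengths a doubling of chromosome 7 was called in 5% of simulations of replicate 1 and 0% of replicate 2 of MCF-10A.

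**Figure D2:**
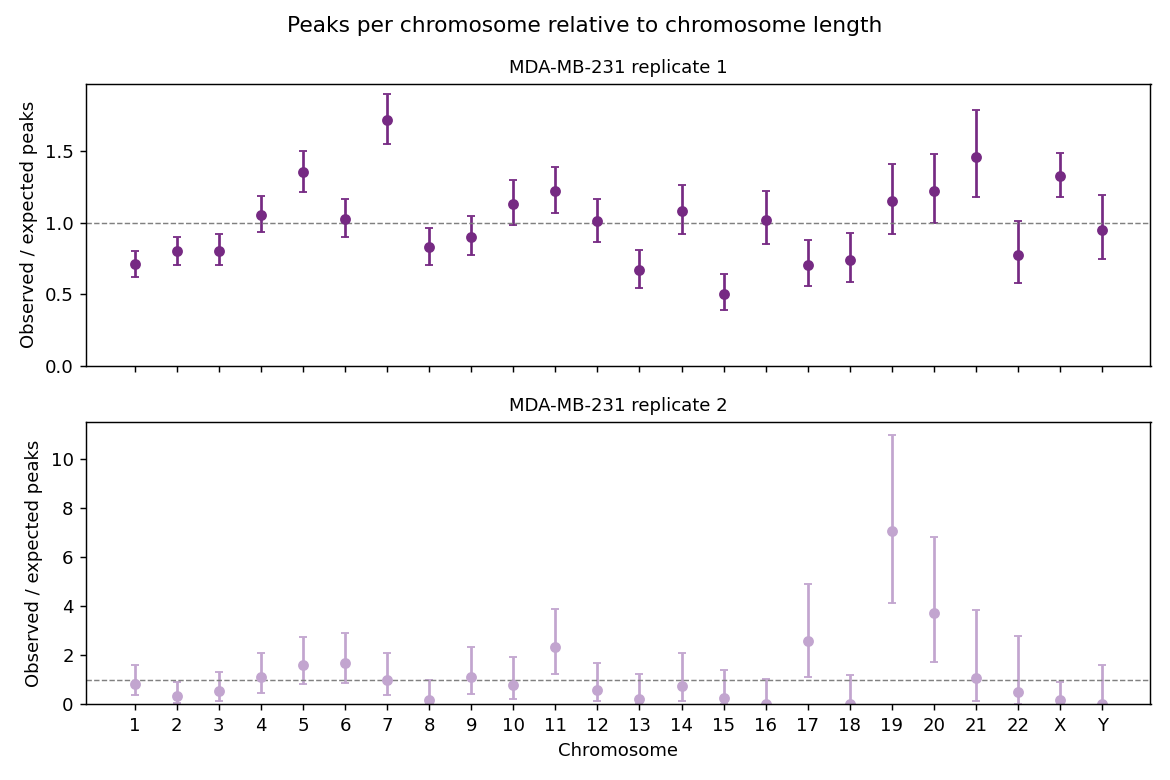
Number of peaks on each chromosome divided by the number its length gives, in replicate 1 (top, 4060 peaks) and replicate 2 (bottom, 119 peaks) of MDA-MB-231, with exact 95% intervals and a dashed line at 1 (the vertical axes differ). Chromosome 7 stands at 1.71 in replicate 1 and 0.981 in replicate 2, and chromosome 19 at 1.15 and 7.04.

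Peaks lay close together along chromosomes in 3 of the 4 libraries. The median distance to the nearest peak of the same library was 52.4 kb in replicate 1 of MCF-10A, against 17655 kb on random placement. It was 112 kb against 252 kb in replicate 1 of MDA-MB-231, and 1678 kb against 5567 kb in replicate 2 of MDA-MB-231 (two-sided permutation of peak positions, adjusted p = 0.00266 for each of the 3, from the smallest p the placements can give). In replicate 2 of MCF-10A it was 8335 kb against 15151 kb, which did not pass (permutation test, adjusted p = 0.14). When peaks within 100 kb were joined, replicate 1 of MDA-MB-231 held 34 regions of 10 or more peaks with 583 peaks in all (14.4%), and the other libraries held 0. The largest was on chromosome 7 from 61054306 to 61839361, with 75 peaks beside the centromere gap. Regions of 34 peaks each lay on chromosome 21 from 10401339 to 11188175 and on chromosome Y from 13642801 to 13862506. As the presence of a Y chromosome in this line was not examined, what the peaks placed on Y stand for is open. Of the 34 regions, 28 lay within 5 Mb of a centromere gap. Whether the others lay beside another large heterochromatin gap was not examined.

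Positions relative to centromere gaps and chromosome ends were compared after the peak positions had been seen. In replicate 1 of MDA-MB-231, 957 of 4060 peaks (23.6%, exact 95% interval 22.3 to 24.9) lay within 5 Mb of a centromere gap, against 7.64% on random placement. With peaks within 100 kb joined to 1 region, the share was 10.3% against 7.15%, still above random (permutation p = 0.002). Near a gap also lay 14 of 42 peaks of replicate 1 of MCF-10A (33.3%, 19.6 to 49.5), against 7.68%. Joined in the same way, 7 of its 28 regions lay there (25.0%), against 8.05% (permutation p = 0.018, not adjusted). Both shares of single peaks passed (two-sided permutation of peak positions, adjusted p = 0.0032 for both, over 8 tests). Among peaks with a score of at least 100, the share was 54.5% in replicate 1 of MCF-10A and 21.3% in replicate 1 of MDA-MB-231. Over all its peaks, replicate 2 of MCF-10A had a share of 10.0% against 8.73% (permutation test, adjusted p = 0.975). In replicate 2 of MDA-MB-231 it was below random, 3 of 119 peaks or 2.52% against 9.27% (permutation test, adjusted p = 0.0107), a call that was lost at distances of 2 and 10 Mb. Within 5 Mb of chromosome ends lay 38.1% of the peaks of replicate 1 of MCF-10A, against 7.46%, and 34.5% of those of replicate 2 of MDA-MB-231, against 9.27% (permutation test, adjusted p = 0.0032 for both). The share was 20.0% against 8.94% in replicate 2 of MCF-10A (permutation test, adjusted p = 0.107). For replicate 1 of MDA-MB-231 it was lower than random, 5.47% against 7.67% (permutation test, adjusted p = 0.0032), and this call was lost at 2 Mb and with peaks within 100 kb joined.

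The replicates of MDA-MB-231 differed from each other in both positions. With each cluster joined to 1 region, 10.3% of the regions of replicate 1 and 2.56% of those of replicate 2 lay near a centromere gap (Fisher's exact test, adjusted p = 0.00775), and 6.14% and 34.2% lay near a chromosome end (adjusted p = 1.09e-17). In MCF-10A the difference near centromere gaps passed on single peaks (33.3% against 10.0%, Fisher's exact test, adjusted p = 0.0346) and not on joined regions (25.0% against 10.0%, adjusted p = 0.173). Peaks within a cluster are not independent, so the value on joined regions is the firmer one. Near chromosome ends the MCF-10A replicates did not differ past the threshold (Fisher's exact test, adjusted p = 0.124 on peaks and 0.0663 on joined regions).

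**Figure D3:**
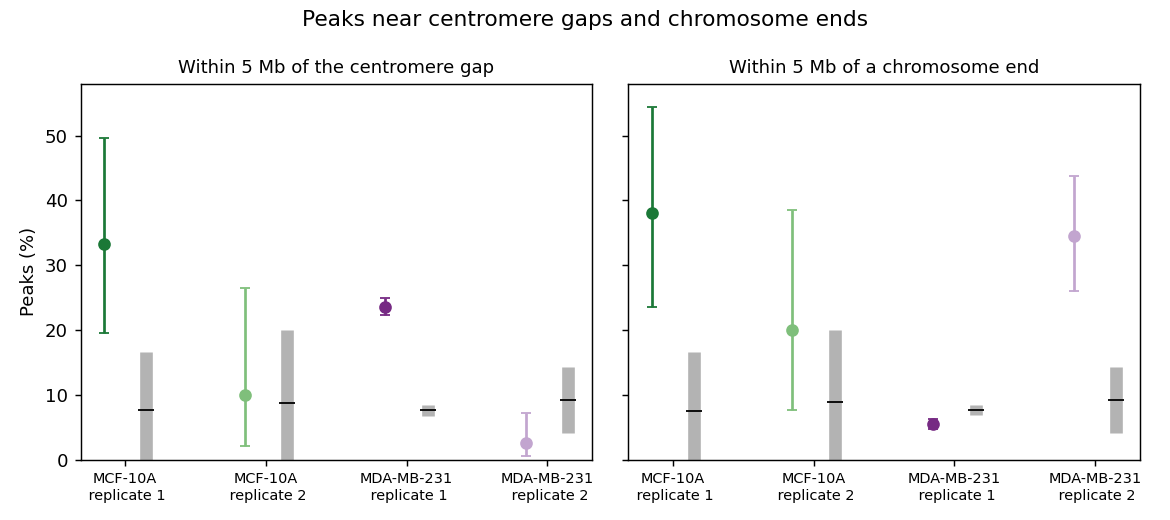
Percentage of peaks within 5 Mb of a centromere gap (left) and of a chromosome end (right) in each nuclear matrix library, as points with exact 95% intervals beside the mean (black dash) and central 95% range (grey bar) of random placements. Near centromere gaps, replicate 1 of MCF-10A (33.3%) and of MDA-MB-231 (23.6%) lie above random, and near ends replicate 1 of MCF-10A (38.1%) and replicate 2 of MDA-MB-231 (34.5%) do.

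**Figure D4:**
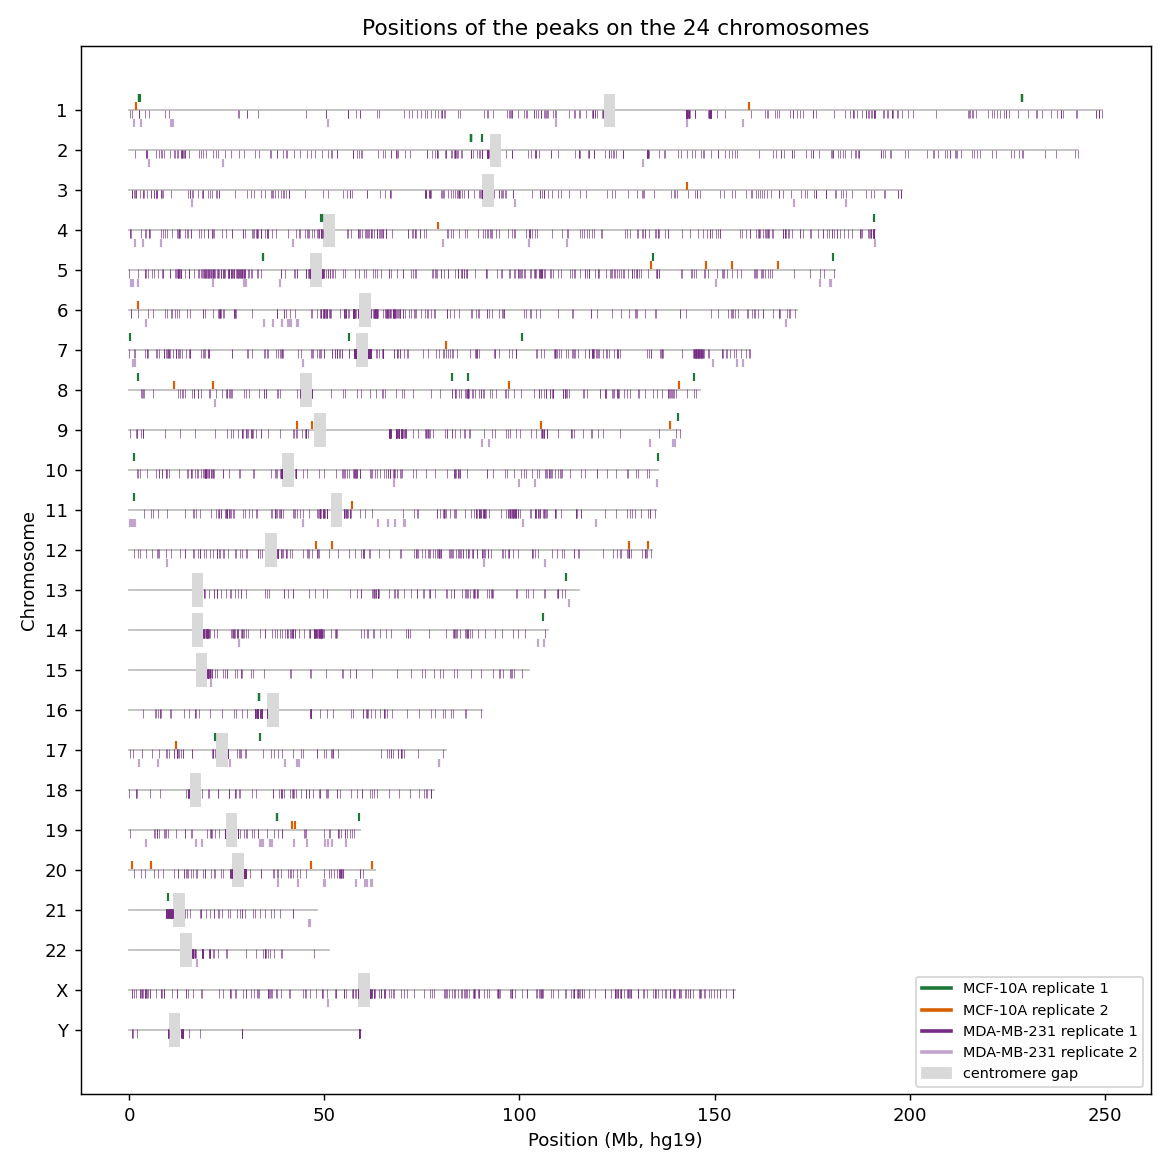
Positions in Mb (hg19) of the peaks of the 4 nuclear matrix libraries on 24 chromosomes, with 1 tick per peak coloured by library and the centromere gap as a grey block. The 4060 peaks of replicate 1 of MDA-MB-231 spread over all 24 chromosomes with clusters beside centromere gaps, such as the 75 peaks on chromosome 7.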

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

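All tests of explanations in this part were chosen after the results had been seen. In replicate 1 of MDA-MB-231, 165 of 4225 peaks (3.90%) lay on 32 unplaced or unlocalised sequences that the comparisons of positions left out. Such peaks were 1 of 43 (2.33%) in replicate 1 and 0 of 30 in replicate 2 of MCF-10A, and 2 of 121 (1.65%) in replicate 2 of MDA-MB-231, so most of the gap in counts follows list length, and the difference in shares was not tested. It is a signal in sequences outside the main comparisons, and no digested nuclei value was at hand to set beside it.

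The first pattern is that the replicates of a line shared no peak. The tables argue against displaced calls of the same regions: within 10 kb of a replicate 1 peak lay 1.68% of the replicate 2 peaks of MDA-MB-231 (exact 95% interval 0.204 to 5.94) and 0 of 30 of MCF-10A. If a less sensitive replicate 2 called a part of the regions of replicate 1, its peaks would touch those regions. Of 119 peaks of MDA-MB-231, 0 touched any of 4060, with an exact upper bound of 3.05%, and in MCF-10A the bound was 11.6%. These counts are the pattern itself and were known before the rule was set. They argue against such partial calling only where the replicate 2 peaks are real, because lists of mostly background calls would also share 0 peaks. The same limit holds for the counts within 10 kb and displaced calls. How far the replicate 2 lists hold background calls was not tested. No biological explanation was tested, since the design gives none for a difference between replicates.

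The second pattern is that replicate 1 of both lines was concentrated near centromere gaps, which was not seen in replicate 2. On joined regions the replicates differed in MDA-MB-231 (10.3% against 2.56%, Fisher's exact test, adjusted p = 0.00775), and in MCF-10A the difference was not shown. A batch shared by libraries of the same number cannot be told apart from other causes, because the libraries numbered 1 shared 3 peaks and those numbered 2 shared 0 peaks, with lists of 30 and 119 peaks. Median scores were also higher in the libraries numbered 1 (70.5 and 73.4) than in those numbered 2 (54.7 and 55.4). Median widths and shares near chromosome ends did not go by number, and scores depend on the unknown read depth. No biological explanation was tested, and neither was the placement of reads of repeated sequence.

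The third pattern is the excess of peaks on 5 chromosomes in replicate 1 of MDA-MB-231, for which clusters beside the centromere, counted as many peaks, are a candidate explanation. Away from the centromere and with clusters counted once, the ratio to the length-based number was 1.43 (exact 95% interval 1.25 to 1.63) for chromosome 5, 1.44 (1.24 to 1.66) for X and 1.23 (1.05 to 1.43, from 1.71) for chromosome 7. Clusters are thus not the whole of the excess on these 3 chromosomes. For chromosome 21 the ratio fell from 1.46 to 0.693 (0.429 to 1.06), or 0.579 (0.367 to 0.866) before joining. The loss of the excess is what the clusters predict. How low the ratio fell was not separated from missing sequence on its short arm, a part of which stayed in the length. For chromosome 11, at 1.11 (0.923 to 1.32) from 1.22, the interval leaves both open. Copy number and the difference between the lines were not tested.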

How the results depend on the processing

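Distances of 2 and 10 Mb, windows of 100 kb and 1 Mb, random placement outside gaps, every alternative to the shares near gaps and ends, leaving out a library for the number of peaks, and the checks of nearby peaks between the libraries numbered 1, were chosen after seeing the data. Of all alternatives, 99 kept the direction and the side of the threshold, or kept a count within 1.5 times. Those that moved a value by less than the spread between replicates are among them. Of the others, 10 reversed the direction, 5 lost a call, 1 gained a call and 5 moved a count further. Among the 99 are short lists and pairs with 0 shared peaks, for which few settings could change the outcome. With the replicate block, which pairs libraries by number, the difference between lines in number of peaks stayed at 4.32 on the log2 scale (SD of the paired differences 3.26, n = 2 pairs, exact sign-flip permutation p = 0.5, the smallest possible), and the numbers are not known to mark a shared batch. Without each library in turn that difference ranged from 1.75 to 6.88. With a score of at least 100, the libraries held 11 and 0 peaks (MCF-10A replicates 1 and 2) and 1261 and 0 (MDA-MB-231), and 4 chromosomes passed in replicate 1 of MDA-MB-231 in place of 13, with fewer peaks tested. Comparisons that need a replicate 2 list had no value at that score. Without each library in turn, the number of peaks shared between lines ranged from 0 to 3, and was 0 without replicate 1 of either line. Leaving out a library was not run for the overlap of replicates, as 1 list would remain. Wider windows turned shared counts above random: within 1 Mb, 2 peaks for the MCF-10A replicates and 94 for those of MDA-MB-231, neither past the threshold. Between replicate 1 of MCF-10A and replicate 2 of MDA-MB-231 there were 2 within 100 kb and 12 within 1 Mb (permutation test, adjusted p = 0.0006 for the latter), and between the libraries numbered 2 there were 2 and 6. Near centromere gaps, replicate 2 of MCF-10A turned below random at 2 Mb (3.33%) and 10 Mb (13.3%), with no call at any distance. The lower share of replicate 2 of MDA-MB-231 was not called at 2 Mb (2.52%) or 10 Mb (16.8%). Near ends, replicate 1 of MDA-MB-231 was not called at 2 Mb (2.78%) or with clusters joined (6.14%), and replicate 2 of MCF-10A was called at 2 Mb (13.3%). Without touching peaks and with placement within 1 Mb, the excess within 10 kb between the libraries numbered 1 was not called (4 peaks). The cause of these changes was not tested. Alternatives for annotation, sequence, gene lists, and the score and width of peaks shared by replicates were not run. Unknown read depth limits every count of peaks.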

Other observations

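The window of 100 kb around peaks, the counts without touching peaks or with joined regions, and the regions in this part were chosen after seeing the data. Some peaks of replicate 1 of MCF-10A lay near, without touching, those of replicate 1 of MDA-MB-231. Within 10 kb there were 7 of 42, the 3 touching ones included, against 1.02 on random placement, and within 100 kb there were 19, against 7.36 (one-sided permutation of peak positions, adjusted p = 0.0006 for both, from the smallest p the placements can give). Without the 3 touching peaks and with placement within 1 Mb, which keeps regional density, 4 of 39 lay within 10 kb, against 1.97 (permutation p = 0.123), and 16 within 100 kb, against 9.52 (permutation p = 0.0067). With the 42 peaks joined to 28 regions and the same placement, 6 lay within 10 kb, against 1.87 (permutation p = 0.004), and 11 within 100 kb, against 6.89 (permutation p = 0.0391). These 4 values are not adjusted, and with placement within 1 Mb the excess within 10 kb was not shown beyond the touching peaks (with placement within the chromosome, 4 against 0.982, permutation p = 0.0144). For the replicates of MDA-MB-231 the same windows held 2 and 15 of 119 peaks, against 3.19 and 22.1, with no excess.

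Small clusters of replicate 1 of MCF-10A, joined within 100 kb, lay on chromosome 1 from 2583370 to 2691895 (4 peaks, highest score 254.1) and on chromosome 2 from 87623587 to 87657033 (4 peaks, highest score 126.1). Clusters of 3 peaks lay on chromosome 1 from 228746610 to 228776687, on chromosome 16 from 33239618 to 33294521 and on chromosome 4 from 49220901 to 49306659. In replicate 1 of MDA-MB-231, a cluster of 23 peaks on chromosome 1 from 142552703 to 142967827 lay 18.02 Mb from the centromere gap. No peak of that library lay between that gap and the cluster. The distance to large heterochromatin gaps apart from the centromere gap was not measured. Whether the cluster lay beside such a gap is therefore open. The 74 peaks of that library on chromosome Y fell into 13 joined regions. Of these peaks 86.5% sat in joined regions of 5 or more, against 20.1% on the other chromosomes, a description without a test. The other libraries held 0 peaks there. Their list lengths would give 0.805, 0.575 and 2.28 if Y were present like the other chromosomes. Whether the lines carry a Y chromosome was not examined, and neither was the placement of reads of repeated sequence. Of the unplaced sequences in replicate 1 of MDA-MB-231, the one with most peaks held 17, with a highest score of 452.5.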
